A study of Homo sapiens with 8 samples.

How the data were processed

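RNA sequencing measured messenger RNA in H2452, an established human cell line grown from a pleural mesothelioma of the biphasic type, a tumour form that holds both epithelioid and sarcomatoid cells. The cells were kept for 48 h with 20 nM deoxypodophyllotoxin (DPT), a plant lignan that binds tubulin and blocks the assembly of microtubules, or with the solvent DMSO. Each group had 4 libraries, which the series design describes as biological replicates. The labels give no culture day or batch and do not pair DPT libraries with DMSO libraries. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected on oligo(dT) beads, and libraries were built with a NEBNext Ultra kit. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping and antisense genes may not be separated.

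The deposited table held 20323 Ensembl genes with symbols, descriptions and pathway and ontology terms, and 2 values per library. The first value was an expected count, per the file headers and the values, since 10.8% of the deposited expected counts were not whole numbers and library totals differed. The other was FPKM, fragments scaled by gene length and library size, which the authors computed, per the file headers. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1, RSEM and DESeq2 were used with the genome build hg38. Their order, roles and settings, the other versions and the annotation release are not given in the sources used here. Estimated counting divides reads between genes of similar sequence, so the values of near-identical genes, such as some tubulin isotypes, and of genes that share a symbol are uncertain.

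Expected counts were rounded to whole numbers. Library totals were 14964432 to 17205391 counts, so that a level of 1 CPM (counts scaled to library size) was about 15 counts in the smallest library. The edgeR package 4.0.16 in R 4.3.3 was used with its filterByExpr defaults (a minimum count of 10 and a minimum total of 15), which kept 12648 genes, and with TMM normalization. DPT was compared with DMSO by edgeR's quasi-likelihood test on all 8 libraries, with an intercept and a treatment term and no other covariate. Adjusted p is the Benjamini-Hochberg value over all tested genes unless stated otherwise, and a gene was called at an adjusted p under 0.05. Genes with an absolute log2 fold change of at least 1 were also counted. Fold changes are DPT over DMSO, SE is the standard error of the fitted log2 fold change, and levels are TMM-normalized CPM given as mean ± SD over the 4 libraries of a group.

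A set of 22 gene lists was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists. Camera with an estimated correlation and fry were run as alternatives. The lists cover mitosis, DNA replication, p53 targets, tubulins, necroptosis machinery, the BCL2 family, NF-kB cytokines, interferon-stimulated genes, the unfolded protein response, the integrated stress and amino acid response, SRF and YAP targets, immediate-early genes, cholesterol synthesis, glycolysis and hypoxia, lysosome and autophagy, ribosome biogenesis, mesothelial or epithelioid markers, sarcomatoid or mesenchymal markers, replication histones, mitochondrial transcripts, leukocyte markers and endothelial markers. Some genes stand on more than 1 list, with 6 such members in the p53 list, 5 in the integrated stress list and 4 in the necroptosis list. KEGG and Gene Ontology terms in the deposited table were tested for over-representation (hypergeometric, one-sided) among the called genes of at least 2-fold against all tested genes that carried a term of the same kind. Terms with 10 to 500 tested members were used, and p was adjusted over 3666 terms and both directions.

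The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 called genes with the largest and the 12 with the smallest log2 fold change among genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It also took the 2 higher and 2 lower called members with the smallest adjusted p of each list, 2 members of each of the 3 leading annotation terms per direction, and RIPK1, RIPK3, MLKL, CASP8, CDKN1A, CCNB1, TUBB, TUBA1B and TUBB2A whether or not they changed. A further 9 genes that set DMSO replicate 3 and DPT replicate 2 apart, and the fibroblast markers of the closing section, were chosen after their values were seen. A few genes that the rule took are not reported here, and none was put in their place.

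These 2 libraries stood apart from the other 6 on the leading principal component of log2 CPM (prior count 2). A term for the pair in the edgeR model, and a fit on the other 6 libraries, were therefore added after the data were seen, and their values are given beside those of the planned fit. Other alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no filter or a stricter filter, the replicate number as a block, each library left out in turn, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in at least 4 libraries, and glmTreat against a fold of 1.5. Log2 changes on the FPKM scales understate the change of low genes. No 2 libraries of a group agreed within sampling noise, so all 8 were kept as separate replicates. The chi-square per degree of freedom over genes with at least 20 counts was 2.66 to 5.33 among the other 6 libraries. Where DMSO replicate 3 or DPT replicate 2 was compared within its group, it was 44.6 to 54.35. These values do not show whether the libraries of a group came from independent cultures, so n counts libraries.

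The scripts were tested on counts simulated from the means, dispersions and sizes of these libraries, with 200 genes changed by known folds. The changed genes had a mean of at least 5 CPM, so the recovery does not hold for lower genes. Counts were drawn gene by gene from the model that was then fitted, with its own dispersions. The false calls thus do not cover variation that genes share in the real libraries. Without a covariate the DPT comparison recovered 50% of genes changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls among 12483 genes. With the term for the pair it recovered 90% at 1.5-fold and 100% at 2-fold, with 18 false calls among 12492 genes. Gene coordinates are from GENCODE release 29 on GRCh38, the assembly also called hg38, in which 99.3% of the gene identifiers were found; they span the whole gene with its exons, introns and untranslated regions and are counted from 1. GC content and length were taken from the longest transcript of each gene there. Figures were drawn with matplotlib 3.10.9.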

Results

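Gene expression was measured in 8 libraries of H2452 mesothelioma cells, 4 from cells kept for 48 h in 20 nM DPT and 4 from cells kept in DMSO. The library totals of DMSO replicates 1 to 4 were 15023306, 14964432, 17205391 and 15528596 counts, and those of DPT replicates 1 to 4 were 16136302, 16524401, 16427053 and 16087550 counts. The group means of 15680431 and 16293826 counts did not differ beyond the spread (two-sided exact permutation test, p = 0.314, n = 4 per group). Of the 20323 genes, 3271 had no counts and 12648 were tested. The 50 most abundant genes took 14.9% ± 0.16 (SD, n = 4) of counts in DMSO and 13.8% ± 0.53 (SD, n = 4) in DPT, and mitochondrial transcripts took 4.17% ± 0.17 and 3.79% ± 0.06. The exact permutation p was 0.0286 for each share, the smallest that 4 against 4 libraries can give.

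A pair of libraries, DMSO replicate 3 and DPT replicate 2, stood apart from the other 6. On the first principal component they scored 40.76 and 29.26, against -25.6 to -1.02 for the others. Interferon-stimulated genes, which antiviral signalling switches on, averaged 6.36 and 5.85 log2 CPM in the pair and 8.09 to 8.19 in the others, and mitosis genes averaged 6.84 and 6.96 against 6.14 to 6.32. On the second component DMSO replicates 1, 2 and 4 scored 23.98 to 25.32, DPT replicates 1, 3 and 4 scored -9.94, -17.63 and -15.34, DMSO replicate 3 scored -0.03 and DPT replicate 2 scored -30.47. Since 1 library of each group stood apart, counts with a term for the pair and counts from the other 6 libraries are given beside those from all 8 for each gene list. The difference between the pair and the others is given as well.

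**Figure D1:**
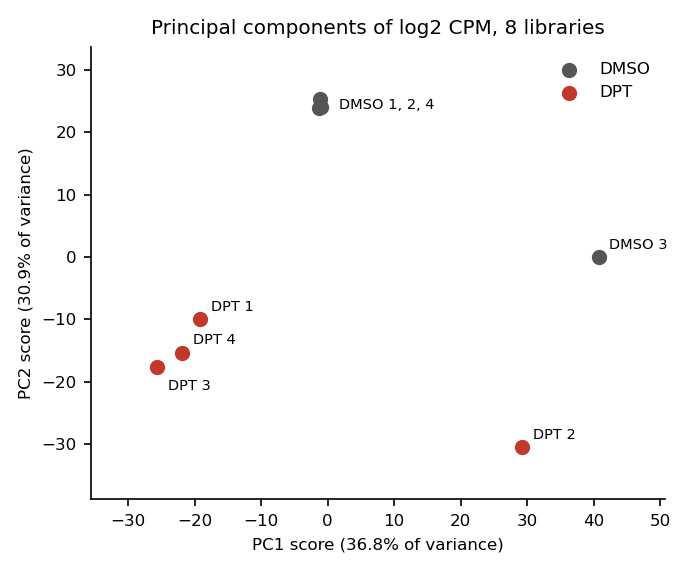
Scores of the 8 libraries on the principal components of log2 CPM, with the share of variance on each axis (36.8% and 30.9%), 1 point per library. DMSO replicate 3 and DPT replicate 2 sit at 40.76 and 29.26 on the first component, apart from the other 6 libraries.

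The comparison of DPT with DMSO asked which messages differ in mesothelioma cells after 48 h with a tubulin binder, and the series names mitosis and necroptosis as processes of interest. IL24, a cytokine of the IL-10 family, rose 9.13-fold from 2.05 ± 0.568 to 18.7 ± 5.57 CPM (mean ± SD, n = 4 per group), IL1A, an inflammatory cytokine, rose 5.16-fold from 5.33 ± 1.44 to 27.4 ± 9.19 CPM, and SERPINB2, an inhibitor of plasminogen activators, rose 4.07-fold from 22.8 ± 2.01 to 92.7 ± 15.4 CPM. ADCYAP1, which encodes the neuropeptide PACAP, fell 3.89-fold from 48.2 ± 3.36 to 12.4 ± 3.35 CPM, and COL3A1, a fibrillar collagen, from 33.0 ± 2.37 to 12.1 ± 3.14 CPM.

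The log2 fold changes were 3.19 (SE 0.281) for IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139 of GRCh38), 2.37 (SE 0.291) for IL1A (ENSG00000115008, chromosome 2, 112773915 to 112784590) and 2.02 (SE 0.123) for SERPINB2 (ENSG00000197632, chromosome 18, 63871692 to 63903890). Their adjusted p values were 0.000434, 0.00183 and 0.000107. ADCYAP1 (ENSG00000141433, chromosome 18, 904943 to 912172) had a log2 fold change of -1.96 (SE 0.161, adjusted p = 0.000318) and COL3A1 (ENSG00000168542, chromosome 2, 188974320 to 189012746) one of -1.45 (SE 0.162, adjusted p = 0.0012). With the term for the pair the values were 3.18, 2.35, 2.02, -1.98 and -1.46. The difference for LCP1, an actin-bundling protein, was smaller within the pair, which holds 1 library of each group, than among the other libraries (interaction of -0.95 log2).

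Other genes with large rises were ESM1, a secreted proteoglycan (log2 fold change 3.45, adjusted p = 0.00602), the collagenase MMP1 (2.74, adjusted p = 0.0111), the extracellular glycoprotein RELN (2.45, adjusted p = 0.00104), SPOCD1 (2.18), TMEM200A (2.06), LCP1 (1.94) and TMEM158 (1.93). CSF2, the growth factor GM-CSF, rose as well (2.06, adjusted p = 0.0197). Among genes that fell were SLC7A4 (-1.71), the heparan sulfate sulfatase SULF1 (-1.60), the GTPase RAB17 (-1.58), the neurexin NRXN3 (-1.51), NANOS1 (-1.49), FAIM2 (-1.78), the deiodinase DIO2 (-1.76) and the zinc finger gene ZSCAN31 (-1.46, adjusted p = 3e-05). ZNF844 had a log2 fold change of 3.65 (adjusted p = 0.017), but 3 genes in the deposited table share its symbol and the identifier ENSG00000286098 was not in the annotation used, so its identity is uncertain. By the rule that chose them, each of these genes had no overlap between the 4 DPT and the 4 DMSO libraries.

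**Figure D2:**
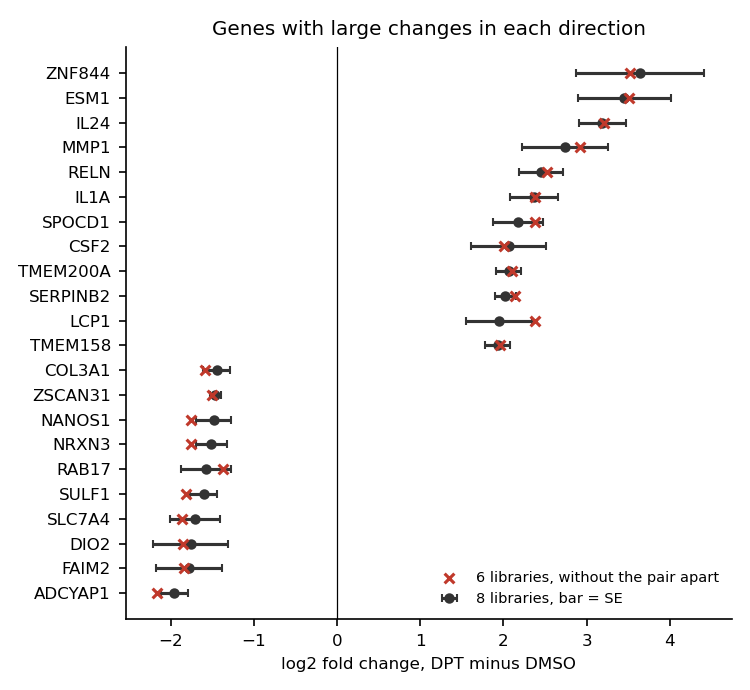
Log2 fold change (DPT minus DMSO, horizontal axis) of 12 genes with large rises and 10 with large falls, with circles and bars for the value and its SE from all 8 libraries and crosses for the value from 6 libraries. Values run from 3.65 for ZNF844 to -1.96 for ADCYAP1. Each cross has the sign of its circle, which follows from the choice of genes without overlap between the groups.

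In all, 718 genes rose and 669 fell in the 8 libraries, of which 143 and 71 changed at least 2-fold. With the term for the pair 2140 rose and 2156 fell (206 and 98 at least 2-fold), and in the 6 other libraries 2158 rose and 2169 fell (277 and 131 at least 2-fold). The term lowered the variation between replicates of a group (biological coefficient) from 14.9% to 6.3%. All 1387 genes called without it were also called with it in the same direction, and 1379 were in the 6 libraries. Of the 385 genes called at 2-fold in the 6 libraries that were also tested with all 8, 335 (87%) differed in the same direction between DPT replicate 2 and DMSO replicate 3, which had no part in that call. In 2305 genes (18.2%) the groups' libraries did not overlap, where chance gives 2.86%.

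The counts changed when single libraries were left out, which also leaves fewer replicates to test with. Without DMSO replicate 3, 859 genes were higher and 877 lower. The genes higher and lower numbered 340 and 312 without DMSO replicate 1, 374 and 353 without DMSO replicate 2, 342 and 331 without DMSO replicate 4, 459 and 434 without DPT replicate 1, 1183 and 1108 without DPT replicate 2, 332 and 314 without DPT replicate 3 and 332 and 311 without DPT replicate 4. Genes higher at 2-fold or more numbered 92, 239, 77 and 80 without DMSO replicate 4, DPT replicate 2, DPT replicate 3 and DPT replicate 4, and those lower 113, 43 and 45 without DPT replicates 2, 3 and 4. The call of CSF2 was lost without DMSO replicates 1 or 2 or DPT replicates 3 or 4 (adjusted p 0.0527 to 0.0638), that of LCP1 without DMSO replicates 1 or 4 (0.0515 to 0.0531), that of FAIM2 without DMSO replicates 1, 2 or 4 or DPT replicate 4 (0.0507 to 0.0693), that of ZNF844 without DPT replicates 3 or 4 (0.054 to 0.0583), and that of DIO2 without any of DMSO replicates 1, 2 and 4 and DPT replicates 1, 3 and 4 (0.0608 to 0.107).

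Immediate-early genes, transcription factors and phosphatases that cells switch on within minutes of a stimulus, rose as a list. Of 23 tested members 15 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.74 and a mean of 0.80 (camera, adjusted p = 2.28e-18; adjusted p = 0.184 with an estimated correlation, in a range of 7.68e-27 to 0.184 over all alternatives). ATF3 rose 2.67-fold from 17.8 ± 1.98 to 47.4 ± 5.3 CPM (n = 4 per group, adjusted p = 0.000231), FOS 3.42-fold from 1.14 ± 0.236 to 3.9 ± 0.614 CPM (adjusted p = 0.00191), and DUSP1, a phosphatase that turns off MAP kinases, 1.87-fold (adjusted p = 0.000559). FOSL2 fell by 0.30 log2 (adjusted p = 0.0179). With the term 19 rose and 1 fell (adjusted p = 0.0111 with an estimated correlation), and in the 6 libraries 18 and 1 (adjusted p = 6.89e-25). Of the 13 lists that passed with the term at the preset correlation, this was the 1 that also passed with an estimated correlation. The list's median was -0.40 log2 in the pair relative to the other 6 libraries, and within the pair DPT replicate 2 exceeded DMSO replicate 3 by a median of 0.84. FOSL2 was not called without any of DMSO replicates 1, 2 and 4 and DPT replicates 3 and 4 (0.0544 to 0.0673).

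NF-kB cytokines, the inflammatory messages controlled by NF-kB, also rose as a list. Of 26 tested members 9 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.50 and a mean of 0.70 (camera, adjusted p = 2.1e-06; adjusted p = 0.597 with an estimated correlation, in a range of 1.77e-16 to 0.597 over all alternatives). IL32 rose 2.01-fold from 13.8 ± 1.83 to 27.8 ± 1.81 CPM (n = 4 per group, adjusted p = 0.000884), beside IL1A. TNFAIP2 fell by 0.55 log2 (adjusted p = 0.0216) and CCL2, a monocyte chemokine, fell by 0.47 log2 (adjusted p = 0.0361). With the term 18 rose and 3 fell (adjusted p = 0.062 with an estimated correlation), as in the 6 libraries (adjusted p = 1.34e-12). In the pair, relative to the others, the list's median was -1.03 log2, and within the pair DPT replicate 2 exceeded DMSO replicate 3 by a median of 0.74. TNFAIP2 was not called without any of DMSO replicates 1, 2 and 4 and DPT replicates 3 and 4 (0.0583 to 0.0711), and CCL2 only without DPT replicate 2 among the 8 fits that left out 1 library (0.0586 to 0.11 in the other 7).

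**Figure D3:**
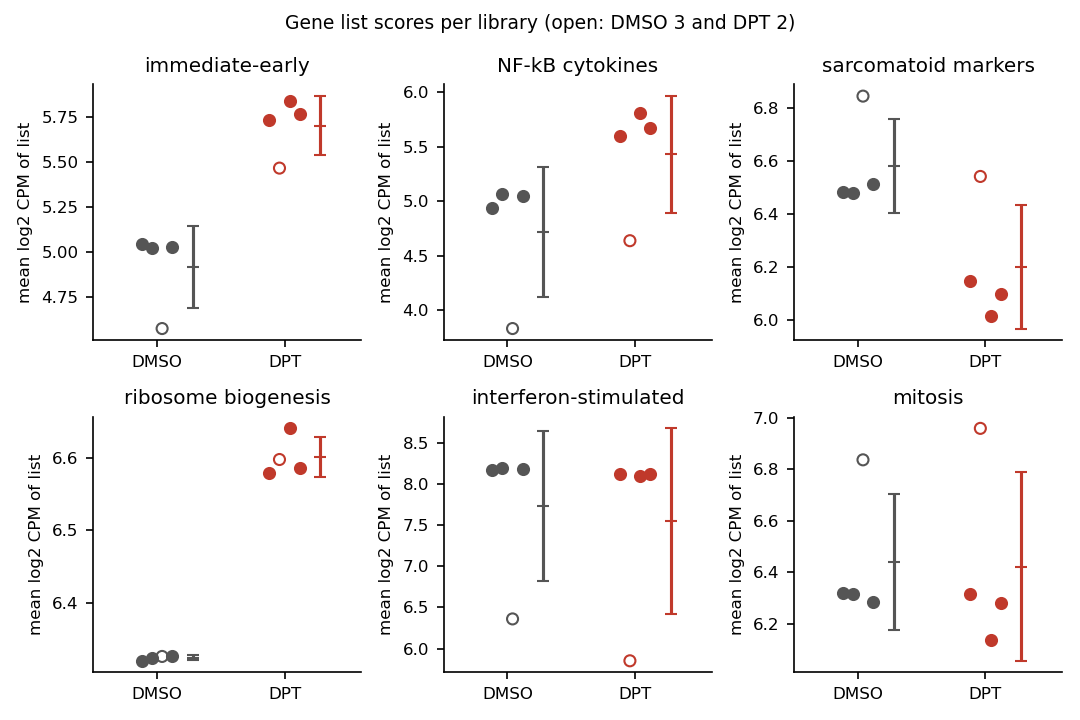
Mean log2 CPM of the tested members of 6 gene lists (vertical axis) in each library, with circles for libraries (open for DMSO replicate 3 and DPT replicate 2) and bars for the mean ± SD of the 4 libraries of a group. Within the filled circles, immediate-early genes, NF-kB cytokines and ribosome biogenesis lie higher in DPT and sarcomatoid markers lower, and the open circles for interferon-stimulated genes lie at 6.36 and 5.85.

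Among KEGG and Gene Ontology terms, 15 were over-represented among genes that rose at least 2-fold and 1 among those that fell (31 and 4 with the term for the pair). Cytokine-cytokine receptor interaction held 12 of its 124 tested genes (7.09-fold, adjusted p = 0.000585), among them IL24, IL32, IL1A and CSF2. Rheumatoid arthritis, a term of cytokines and matrix proteases, held 8 of 55 (adjusted p = 0.0022), cellular response to lipopolysaccharide 9 of 110 (adjusted p = 0.00718) and TNF signaling 8 of 97 (adjusted p = 0.03). Cell adhesion was the term among genes that fell, with 12 of 373 (5.55-fold, adjusted p = 0.00319). Its members included the integrins ITGB8 (42.9 ± 3.57 to 19.3 ± 1.24 CPM, n = 4 per group, adjusted p = 0.000159) and ITGA11 (28.2 ± 2.72 to 12.95 ± 0.886 CPM, adjusted p = 0.000416) and NRXN3. The numbers of terms for rises and falls were 0 and 0 without DMSO replicate 1, DPT replicate 3 or DPT replicate 4, 7 and 0 without DMSO replicate 2, 24 and 10 without DMSO replicate 3, 9 and 0 without DMSO replicate 4, 6 and 1 without DPT replicate 1 and 54 and 14 without DPT replicate 2.

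Ribosome biogenesis genes, which make and process ribosomal RNA, rose by small amounts. Of 30 tested members 14 rose and 0 fell (23 and 0 adjusted over the list alone), 29 had a positive log2 fold change, and the median was 0.31 and the mean 0.28 (camera, adjusted p = 7.26e-11). Before adjustment, at p under 0.05, edgeR gave 23 higher and 0 lower, DESeq2 gave 18 and 0 after adjustment and limma 16 and 0. The RNA helicase DDX21 rose 1.38-fold from 371.8 ± 10.1 to 511 ± 32.1 CPM (n = 4 per group, adjusted p = 0.00318) and RRP12 rose 1.33-fold from 64.1 ± 1.79 to 84.9 ± 3.82 CPM (adjusted p = 0.00361). This was the only list of the 22 that passed with an estimated correlation (adjusted p = 0.0167). With the term 26 rose and 1 fell (adjusted p = 2.53e-11, and adjusted p = 0.062 with an estimated correlation). In the 6 libraries 27 rose and 1 fell (adjusted p = 3.65e-09). The list's median was 0.02 log2 in the pair relative to the others.

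Markers of the sarcomatoid, mesenchymal form of mesothelioma fell as a list. Of 24 tested members 1 rose and 7 fell (1 and 11 adjusted over the list alone), with a median log2 fold change of -0.37 and a mean of -0.37 (camera, adjusted p = 1.87e-06; adjusted p = 0.442 with an estimated correlation, in a range of 3.46e-10 to 0.442 over all alternatives). COL1A2, a chain of type I collagen, went from 324.1 ± 21.6 to 138.3 ± 31.4 CPM (n = 4 per group, adjusted p = 0.00157), and PDGFRB, a growth factor receptor of mesenchymal cells, from 54.8 ± 7.15 to 22.3 ± 3.69 CPM (adjusted p = 0.000884), beside COL3A1. The intermediate filament VIM rose 1.38-fold from 5277 ± 761 to 7278 ± 537 CPM (adjusted p = 0.0182). With the term 4 rose and 16 fell (adjusted p = 0.0829 with an estimated correlation). In the 6 libraries 6 rose and 16 fell (adjusted p = 3.24e-08). In the pair, relative to the others, the list's median was 0.34 log2. VIM was not called without any of DMSO replicates 1, 2 and 4 (0.059 to 0.0653).

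Mesothelial and epithelioid markers did not pass camera with all 8 libraries (median -0.34, mean -0.13, adjusted p = 0.0553; adjusted p = 0.43 with an estimated correlation, in a range of 0.00202 to 0.43 over all alternatives). Of 20 tested members 0 rose and 2 fell (2 and 7 adjusted over the list alone). With no adjustment (p under 0.05), edgeR gave 3 higher and 9 lower, and after adjustment DESeq2 gave 1 and 6 and limma 0 and 2. The keratin KRT18 fell by 0.65 log2 from 1171 ± 186 to 746.2 ± 117 CPM (n = 4 per group, adjusted p = 0.0149) and the uroplakin UPK3B fell by 1.07 log2 (adjusted p = 0.0271). The list passed with the term (4 higher and 10 lower, adjusted p = 0.00851, and adjusted p = 0.0964 with an estimated correlation), in the 6 libraries (4 higher and 11 lower, adjusted p = 0.00926), without DMSO replicate 1 (adjusted p = 0.0416) and without DMSO replicate 4 (adjusted p = 0.0493). Its median was 0.06 log2 in the pair relative to the others. KRT18 was not called without DPT replicates 3 or 4 (0.0519 to 0.0561) and UPK3B not without DMSO replicates 1 or 4 or DPT replicates 1 or 3 (0.0649 to 0.0841).

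Targets of SRF and YAP, which answer to the actin cytoskeleton and to cell tension, fell as a list. Of 28 tested members 0 rose and 6 fell (0 and 7 adjusted over the list alone), with a median of -0.08 and a mean of -0.06 (camera, adjusted p = 0.0388; adjusted p = 0.597 with an estimated correlation, in a range of 0.00155 to 0.597 over all alternatives). At an unadjusted p under 0.05, edgeR gave 1 higher and 7 lower, and after adjustment DESeq2 gave 0 and 7 and limma 0 and 3. AJUBA, a scaffold at cell junctions, fell by 0.62 log2 from 102.2 ± 3.24 to 66.6 ± 2.21 CPM (n = 4 per group, adjusted p = 0.000483) and CRIM1 fell by 0.71 log2 from 749.7 ± 50.2 to 459.2 ± 55.4 CPM (adjusted p = 0.00245). The fall of CRIM1 was smaller within the pair, which holds 1 library of each group, than among the other libraries (interaction of 0.51 log2). With the term 6 rose and 11 fell (adjusted p = 0.48 with an estimated correlation). In the 6 libraries 5 rose and 12 fell (adjusted p = 0.00155). The list's median was 0.09 log2 in the pair relative to the others. The list did not pass without DMSO replicate 3 (adjusted p = 0.123), DPT replicate 1 (0.0745), DPT replicate 3 (0.0968) or DPT replicate 4 (0.12).

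Mitosis genes did not shift as a list. Of 38 tested members 0 rose and 1 fell (0 and 0 adjusted over the list alone), the median of 0.03 and the mean of 0.001 were positive and the test pointed down (camera, adjusted p = 0.809; adjusted p = 0.95 with an estimated correlation, in a range of 0.00409 to 0.95 over all alternatives). With no adjustment (p under 0.05), edgeR gave 1 higher and 1 lower, and after adjustment DESeq2 gave 0 and 1 and limma 0 and 0. CCNB1, the cyclin of mitotic entry, measured 219.8 ± 72.3 CPM in DMSO and 262.1 ± 108 CPM in DPT (n = 4 per group, log2 fold change 0.25, adjusted p = 0.621), and with the term it rose by 0.23 log2 (adjusted p = 0.00238). INCENP, a subunit of the Aurora B complex, fell by 0.36 log2 (adjusted p = 0.0493), a call that held without DPT replicate 2 and was lost without any other single library (0.0705 to 0.137). With the term 7 members rose and 6 fell (adjusted p = 0.9), and in the 6 libraries 3 and 8 (adjusted p = 0.244). The list was lower without DPT replicate 2 (adjusted p = 0.00409). In that fit DMSO replicate 3 has no counterpart, so its own difference enters the comparison. In the pair, relative to the others, the list's median was 0.61 log2.

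DNA replication genes fell by small amounts as a list with all 8 libraries. Splitting the libraries into 4 and 4 gave as small a camera p in 15 of 35 splits, the real one included. Of 41 tested members 0 rose and 3 fell (0 and 3 adjusted over the list alone), with a median of -0.17 and a mean of -0.14 (camera, adjusted p = 0.00408; adjusted p = 0.718 with an estimated correlation, in a range of 1.12e-06 to 0.718 over all alternatives). At an unadjusted p under 0.05, edgeR gave 0 higher and 10 lower, and after adjustment DESeq2 gave 0 and 6 and limma 0 and 2. The helicase subunits MCM6 and MCM2 fell by 0.44 log2 (138.7 ± 2.91 to 101.9 ± 7.26 CPM, n = 4 per group, adjusted p = 0.00372) and by 0.30 log2 (adjusted p = 0.017). The other member that fell, MCM7, was chosen after its values were seen. With the term 0 rose and 18 fell (adjusted p = 0.427 with an estimated correlation). In the 6 libraries 0 rose and 22 fell (adjusted p = 0.000154). The list's median was 0.28 log2 in the pair relative to the others, and the list did not pass without DMSO replicate 3 (adjusted p = 0.104). MCM2 was not called without DMSO replicates 2 or 4 or DPT replicates 3 or 4 (0.0528 to 0.0636). Of 9 tested replication histones 0 rose and 0 fell (0 and 0 adjusted over the list alone; median 0.02, mean 0.08, camera up, adjusted p = 0.624). With no adjustment (p under 0.05), edgeR gave 2 histones higher and 0 lower, and after adjustment DESeq2 gave 1 and 0 and limma 1 and 0. With the term 2 histones rose and 2 fell, as in the 6 libraries, and their median was -0.45 log2 in the pair relative to the others. Reads of histone messages without a tail of adenines are lost in the oligo(dT) selection.

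Targets of p53 rose as a list through a few members. Of 32 tested members 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.02 and a mean of 0.17 (camera, adjusted p = 0.0148; adjusted p = 0.442 with an estimated correlation, in a range of 0.00239 to 0.442 over all alternatives). At an unadjusted p under 0.05, edgeR gave 8 higher and 1 lower, and after adjustment DESeq2 gave 5 and 0 and limma 5 and 0. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 2.38-fold from 17.3 ± 3.07 to 41.0 ± 5.98 CPM (n = 4 per group, adjusted p = 0.00166). The nuclease AEN rose 1.73-fold from 55.1 ± 3.45 to 95.1 ± 6.12 CPM (adjusted p = 0.00049) and GADD45A, a growth arrest gene, 1.58-fold (adjusted p = 0.00133). The others that rose were SESN2 and PLK3, the latter chosen after its values were seen. With the term 8 rose and 2 fell (adjusted p = 0.142 with an estimated correlation), and in the 6 libraries 7 and 2 (adjusted p = 0.00581). The list's median was -0.11 log2 in the pair relative to the others.

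Tubulin messages did not change as a list in the 8 libraries. Of 11 tested isotypes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.11 and a mean of -0.05 (camera, down, adjusted p = 0.624; adjusted p = 0.95 with an estimated correlation). With no adjustment (p under 0.05), edgeR gave 1 higher and 1 lower, and after adjustment DESeq2 gave 0 and 1 and limma 0 and 0. TUBB measured 1962 ± 317 CPM in DMSO and 1390 ± 289 CPM in DPT (n = 4 per group, log2 fold change -0.50, adjusted p = 0.0672), TUBA1B 1976 ± 490 and 1540 ± 398 CPM (-0.36, adjusted p = 0.287), and TUBB2A 21.97 ± 10.2 and 27.4 ± 5.6 CPM (0.31, adjusted p = 0.515). With the term 3 isotypes rose and 4 fell (list adjusted p = 0.104), among them TUBB (-0.50, adjusted p = 1.22e-06), TUBA1B (-0.36, adjusted p = 1.34e-05) and TUBB2A (0.37, adjusted p = 0.0114), beside TUBA4A and TUBB3, which fell, and TUBB6 and TUBB2B, which rose and were chosen with them after their values were seen. As many rose and fell in the 6 libraries (adjusted p = 0.321). Without DPT replicate 2 TUBB and TUBA1B were lower (adjusted p = 0.00681 and 0.0415), and without DMSO replicate 3 TUBB2A was higher (adjusted p = 0.0199). These fits leave 1 library of the pair without a counterpart, so they do not bear on the calls with the term. In the pair, relative to the others, the list's median was 0.52 log2. Some tubulin isotypes are near-identical in sequence, and the division of reads between those is uncertain.

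Genes of the necroptosis machinery, the pathway of regulated necrosis, passed the list test upward by a small amount with all 8 libraries. A camera p as small came from 16 of the 35 splits of the libraries into 4 and 4, the real one included. Of 25 tested members 4 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.11 and a mean of 0.14 (camera, adjusted p = 0.0388; adjusted p = 0.693 with an estimated correlation, in a range of 0.00409 to 0.693 over all alternatives). The members that rose were not the kinases of the pathway: BIRC3, a ubiquitin ligase that restrains cell death, rose 1.98-fold from 36.8 ± 7.11 to 72.7 ± 19.1 CPM (n = 4 per group, adjusted p = 0.0171), and TICAM1, an adaptor of Toll-like receptors, rose 1.38-fold (adjusted p = 0.0143). The others that rose, BIRC2 and SPATA2, were chosen after their values were seen. The TNF receptor TNFRSF1A fell by 0.45 log2 from 245 ± 23.3 to 179.6 ± 12.4 CPM (adjusted p = 0.011). RIPK1 measured 56.5 ± 0.991 CPM in DMSO and 56.5 ± 1.7 CPM in DPT (adjusted p = 0.997), and CASP8, the protease that restrains necroptosis, 46.8 ± 4.17 and 44.3 ± 5.33 CPM (adjusted p = 0.678). MLKL, the protein that breaks the membrane, measured 21.2 ± 5.27 and 33.1 ± 6.46 CPM (log2 fold change 0.65, adjusted p = 0.0712), and rose with the term by 0.65 log2 (adjusted p = 9.23e-06) and without DPT replicate 2 by 0.78 log2 (adjusted p = 0.015), where DMSO replicate 3 has no counterpart. MLKL was called higher in 6 of 18 alternative fits, DESeq2 and limma-trend on either FPKM scale among them, and was not called in the others.

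RIPK3, the kinase that activates MLKL, had 0 counts in the 4 DMSO libraries and 0 in the 4 DPT libraries, out of 62721725 and 65175306 counts, which allows a level of up to 0.0478 and 0.046 CPM (3 counts over each group, counting error only), so its message was not detectable at this depth. The necroptosis list did not pass with the term (9 higher and 3 lower, adjusted p = 0.0562), in the 6 libraries (9 and 3, adjusted p = 0.122), or without DMSO replicate 3 (0.304), DPT replicate 1 (0.0924), DPT replicate 3 (0.0752) or DPT replicate 4 (0.0554). Its median was -0.25 log2 in the pair relative to the others. BIRC3 was not called without DMSO replicate 2 or DPT replicates 3 or 4 (0.0525 to 0.0581), and TICAM1 not without DMSO replicate 4 or DPT replicate 3 (0.0512 to 0.0528). In the BCL2 family, which governs mitochondrial apoptosis, 1 of 14 tested members rose and 0 fell (0 and 0 adjusted over the list alone; median 0.06, mean 0.14, camera up, adjusted p = 0.539). That member was the death effector BAK1 (log2 fold change 0.35, adjusted p = 0.0442), not called without any of DMSO replicates 1, 2 and 3 and DPT replicates 1, 3 and 4 (0.0717 to 0.128). At an unadjusted p under 0.05, edgeR gave 1 higher and 0 lower of the family, and after adjustment DESeq2 gave 2 and 0 and limma 1 and 0. The family's median was -0.42 log2 in the pair relative to the others, and with the term 5 rose and 1 fell, as in the 6 libraries.

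Genes of the integrated stress and amino acid response rose as a list with all 8 libraries. As small a camera p came from 15 of the 35 splits of the libraries into 4 and 4, the real one included. Of 30 tested members 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.16 and a mean of 0.21 (camera, adjusted p = 0.00599; adjusted p = 0.718 with an estimated correlation, in a range of 9.17e-06 to 0.718 over all alternatives). Beside ATF3, the stress sensor SESN2 rose 1.99-fold from 18.8 ± 3.09 to 37.3 ± 4.23 CPM (n = 4 per group, adjusted p = 0.0028), and the cystine transporter SLC7A11 fell by 0.24 log2 (adjusted p = 0.0405). SLC3A2, an amino acid transporter subunit chosen after its values were seen, was the other member that rose. With the term 15 rose and 3 fell (adjusted p = 0.118 with an estimated correlation). In the 6 libraries 13 rose and 6 fell (adjusted p = 0.000715). The list's median was -0.45 log2 in the pair relative to the others, and the list did not pass without DMSO replicate 3 (adjusted p = 0.272). Of 24 tested genes of the unfolded protein response 1 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.07, mean 0.10, camera up, adjusted p = 0.449). PPP1R15A, which ends the stress block on translation, rose 2.37-fold from 65.4 ± 10.9 to 154.8 ± 28 CPM (adjusted p = 0.00198) and SEL1L fell by 0.27 log2 (adjusted p = 0.0139). With the term 9 rose and 8 fell, in the 6 libraries 9 and 7, and this list's median was 0.04 log2 in the pair relative to the others. SLC7A11 was not called without any of DMSO replicates 1, 2 and 4 and DPT replicates 1, 3 and 4 (0.0728 to 0.126), and SEL1L not without DMSO replicate 1 or DPT replicate 3 (0.05 to 0.055).

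Cholesterol synthesis genes rose by small amounts as a list with all 8 libraries, but 17 of the 35 splits of the libraries into 4 and 4, the real one included, gave as small a p. Of 24 tested members 4 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.08 and a mean of 0.10 (camera, adjusted p = 0.0388; adjusted p = 0.597 with an estimated correlation, in a range of 0.0163 to 0.597 over all alternatives). IDI1 rose 1.26-fold from 46.7 ± 1.88 to 58.8 ± 3.12 CPM (n = 4 per group, adjusted p = 0.0129), NSDHL rose 1.3-fold (adjusted p = 0.0154), and TM7SF2, a sterol reductase, fell by 0.66 log2 (adjusted p = 0.0345). SQLE, chosen after its values were seen, also rose. With the term 10 rose and 2 fell (adjusted p = 0.456 with an estimated correlation), and in the 6 libraries, with 9 and 2, the list did not pass (adjusted p = 0.184). It did not pass either without DMSO replicate 3 (0.304), DPT replicate 1 (0.0949), DPT replicate 3 (0.0504) or DPT replicate 4 (0.0503). Its median was -0.12 log2 in the pair relative to the others. NSDHL was not called without DMSO replicates 1, 2 or 4 (0.05 to 0.0557), and TM7SF2 not without any of DMSO replicates 1, 2 and 4 and DPT replicates 1, 3 and 4 (0.0576 to 0.0972).

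Glycolysis and hypoxia genes, with 2 of 31 tested members higher and 1 lower (3 and 2 adjusted over the list alone), did not shift as a list (median -0.02, mean 0.02, camera up, adjusted p = 0.809). HK2, the hexokinase of glycolysis, rose by 0.43 log2 (86.3 ± 6.71 to 116.3 ± 12.1 CPM, n = 4 per group, adjusted p = 0.016), BNIP3 by 0.23 log2 (adjusted p = 0.041), and the glucose transporter SLC2A1 fell by 0.36 log2 (adjusted p = 0.0337). Lysosome and autophagy genes, with 1 of 31 higher and 1 lower (4 and 4 adjusted over the list alone), did not shift either (median -0.07, mean -0.01, camera down, adjusted p = 0.809). MAP1LC3B, the autophagosome marker, rose 1.38-fold from 182.2 ± 3.43 to 251.2 ± 26.6 CPM (adjusted p = 0.00703) and the lysosomal membrane protein LAMP2 fell by 0.23 log2 (adjusted p = 0.0355). With the term 7 rose and 8 fell in the first list and 8 and 7 in the second. In the 6 libraries these were 7 and 10 and 7 and 13. The lists' medians in the pair relative to the others were 0.13 and -0.08 log2. The calls were lost for HK2 without DPT replicates 3 or 4 (0.0525 to 0.0542), for BNIP3 without any library except DPT replicate 2 (0.065 to 0.126), for SLC2A1 without any except DMSO replicate 2 and DPT replicate 2 (0.0513 to 0.107), and for LAMP2 without any except DMSO replicate 3 and DPT replicate 2 (0.0685 to 0.112).

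Interferon-stimulated genes differed mainly between the pair of libraries and the other 6, with a median of -2.01 log2 in the pair. Between DPT and DMSO 0 of 38 tested members rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.14 and a mean of -0.11 (camera, down, adjusted p = 0.539; adjusted p = 0.95 with an estimated correlation, in a range of 2.46e-05 to 0.97 over all alternatives). With no adjustment (p under 0.05), edgeR gave 0 higher and 0 lower, and DESeq2 and limma gave 0 and 0 after adjustment. With the term 1 rose and 20 fell (adjusted p = 2.46e-05, and adjusted p = 0.465 with an estimated correlation), and in the 6 libraries 6 rose and 17 fell (adjusted p = 0.0207). It was lower without DMSO replicate 3 (adjusted p = 0.00917). In this fit DPT replicate 2 has no counterpart, so the difference of the pair enters the comparison. Of the genes chosen after their values were seen, the ubiquitin-like ISG15 measured 46.4 and 39.6 CPM in the pair and 243.8 to 311.2 CPM in the others, and IFITM1, an antiviral membrane protein, 53.3 and 36.5 against 369.8 to 557.9 CPM. CYP1A1, a target of the aryl hydrocarbon receptor, measured 24.8 and 21.1 CPM in the pair and 1.63 to 2.70 CPM in the others.

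**Figure D4:**
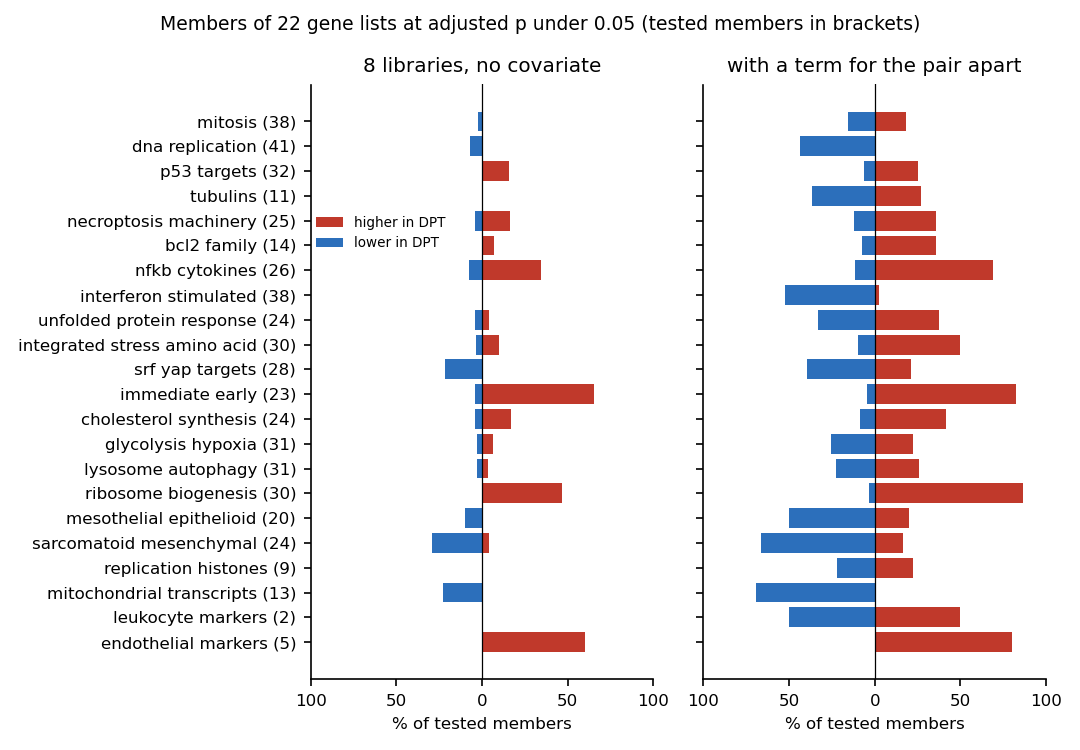
Share of each list's tested members (in brackets) that were higher (right) or lower (left) in DPT at an adjusted p under 0.05, in % on the horizontal axis, from the 8 libraries with no covariate and with the term for the pair. Immediate-early genes have 15 higher and 1 lower of 23, and interferon-stimulated genes go from 0 and 0 to 1 and 20 of 38 with the term.

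Mitochondrial transcripts fell as a list, with 0 of 13 tested members higher and 3 lower (0 and 7 adjusted over the list alone), a median of -0.21 and a mean of -0.23 (camera, adjusted p = 0.0101; adjusted p = 0.597 with an estimated correlation, in a range of 0.000599 to 0.597 over all alternatives). At an unadjusted p under 0.05, edgeR gave 0 higher and 8 lower, and after adjustment DESeq2 gave 0 and 7 and limma 0 and 0. MT-ND5, a subunit of respiratory complex I, fell by 0.28 log2 from 3226 ± 117 to 2654 ± 167 CPM (n = 4 per group, adjusted p = 0.0206) and MT-ND6 fell by 0.33 log2 (adjusted p = 0.0441). MT-CO1, chosen after its values were seen, was the other member that fell. With the term 0 rose and 9 fell (adjusted p = 0.456 with an estimated correlation), and in the 6 libraries 0 and 10 (adjusted p = 0.00371). The median in the pair relative to the others was -0.06 log2. The list did not pass without DMSO replicate 2 (adjusted p = 0.0612), MT-ND5 was not called without any of DMSO replicates 1, 2 and 4 and DPT replicates 3 and 4 (0.0543 to 0.0727), and MT-ND6 not without any of DMSO replicates 1 and 2 and DPT replicates 1, 3 and 4 (0.0755 to 0.132).

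Markers of other cell types were mostly too low to test. Of 18 leukocyte markers 2 were tested, and 0 rose and 0 fell (0 and 0 adjusted over the list alone; median -0.17, mean -0.17, camera up, adjusted p = 0.896). With no adjustment (p under 0.05), edgeR gave 0 leukocyte markers in either direction, and DESeq2 and limma gave 0 after adjustment. With the term 1 rose and 1 fell, as in the 6 libraries, and their median was -1.03 log2 in the pair. Of 13 endothelial markers 5 were tested, of which 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.98, mean 1.24, camera, adjusted p = 0.00324; adjusted p = 0.442 with an estimated correlation, in a range of 1.06e-06 to 0.442 over all alternatives). At an unadjusted p under 0.05, edgeR gave 4 endothelial markers higher and 0 lower, and after adjustment DESeq2 gave 3 and 0 and limma 1 and 0. The guidance receptor ROBO4 rose 2.91-fold from 4.37 ± 0.901 to 12.7 ± 4.25 CPM (n = 4 per group, adjusted p = 0.00879), and KDR, a receptor of vascular growth factors, rose from 0.415 ± 0.201 to 2.54 ± 1.74 CPM (adjusted p = 0.0257). TIE1, chosen after its values were seen, was the other marker that rose. With the term 4 endothelial markers rose (adjusted p = 0.0964 with an estimated correlation), as in the 6 libraries (adjusted p = 0.00155), and their median was -0.89 log2 in the pair relative to the others. KDR was not called without any of DMSO replicates 1, 2 and 4 and DPT replicates 1, 3 and 4 (0.0555 to 0.0694).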

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

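Of the tests reported in this part, that for another cell line and that for a culture batch were chosen only after the result was seen. A library's value was singled out where its gap to the nearest other library of the same group was large against the whole range of the 4 libraries (Dixon's criterion at 95%). Of 176 groups of values tested, 45 met it, where chance gives about 1 in 20 groups, or 9. They included genes named because they set DMSO replicate 3 and DPT replicate 2 apart, so their number overstates how often a library stands out.

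DMSO replicate 3 was far above the other DMSO libraries, with this gap as a share of the range, for LCP1 (0.979), DIO2 (0.941), RAB17 (0.984), KRT18 (0.86), VIM (0.893), CCNB1 (0.913), TUBB (0.843), TUBA1B (0.913), TUBB2A (0.866), THBS1 (0.962), SPDL1 (0.971), ANLN (0.961), CYP1A1 (0.953) and the mean of the mitosis genes (0.938). It was far below them for TMEM158 (0.848), TNFAIP2 (0.845), SESN2 (0.853), KDR (0.841), IFITM1 (0.917), SOD2 (0.9), ISG15 (0.87), IFI44L (0.92), MX2 (0.993) and the mean of the interferon-stimulated genes (0.989). DPT replicate 2 was far above the other DPT libraries for DIO2 (0.913), CCNB1 (0.886), THBS1 (0.953), SPDL1 (0.936), ANLN (0.919) and CYP1A1 (0.974). It was far below them for SESN2 (0.909), MLKL (0.851), CASP8 (0.84), CDKN1A (0.843), IFITM1 (0.861), SOD2 (0.89), ISG15 (0.891), IFI44L (0.937), MX2 (0.988) and the mean of the interferon-stimulated genes (0.989).

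Single values stood out in other libraries too. ZNF844 was far higher in DMSO replicate 4 than in the other DMSO libraries (0.831), and FOS in DMSO replicate 1 (0.875). MCM2 was far higher in DPT replicate 1 than in the other DPT libraries (0.856), as was the share of mitochondrial counts (0.917), and IL32 was far higher in DPT replicate 3 (0.846).

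DMSO replicate 3 and DPT replicate 2 shared lower interferon-stimulated genes, with a median log2 difference of -2.01 from the other 6 libraries (SD over members 0.65). Sequence bias is argued against as the whole cause, since the median was -2 after removal of GC content and length trends. After thinning every library to the smallest total the median was -2.01. Library totals ran only from 14964432 to 17205391 counts, so thinning could hardly move the median and was no real test of depth. The tables also argue against another cell line, as 0 genes stood at 5 CPM or more in one set and at most 0.1 CPM in every library of the other, and against a swap between DPT and DMSO, as 100% of 24 genes chosen on the other 6 libraries differed within the pair as between the groups. A culture or handling batch that the labels do not give may be the source. The deviations of the pair from their group means correlated across genes (r = 0.68, where genes are not independent replicates). The pair was picked because both libraries stood apart, so this correlation cannot tell a batch from another shared cause. A batch stays open because the labels give none, and no biological explanation was tested, since the design gives none.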

How the results depend on the processing

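The fits with a term for DMSO replicate 3 and DPT replicate 2 and without those libraries were chosen after the data were seen. No named gene or list that was called reversed its direction under any alternative (0 reversals). With RLE size factors 82 named genes and 22 lists kept their direction and their side of the threshold. DESeq2 lost 0 and gained 2 of the named genes, library totals alone lost 4 (969 genes higher and 523 lower), no filter lost 3, the stricter filter lost 0, and limma-trend on either FPKM scale lost 9. Where no cause is named, the cause was not tested.

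DESeq2 gave 30 annotation terms for rises and 3 for falls. Limma-trend on log2(FPKM + 1) gave 335 genes lower, 58 higher and 17 lower at 2-fold, 0 terms for falls, and an adjusted p of 0.0853 for the p53 list; on log2(FPKM + 0.1) these were 335, 92, 40, 0 and 0.0861, with 3 terms for rises. The pseudocount shrinks the changes of low genes by construction. The test against a fold of 1.5 (glmTreat), which is stricter than the planned test by construction, gave 43 genes higher and 21 lower. These were counted without the 2-fold filter. The replicate number as a block gave 171 genes higher and 174 lower, 69 and 42 at 2-fold and 0 and 0 terms, and lost 28 of the named genes, where edgeR gave 3357 genes at an unadjusted p under 0.05 without a block. With the block SRF and YAP targets (adjusted p = 0.0745) and cholesterol synthesis (0.0643) lost their call as lists, mesothelial markers gained one (0.0492), and 19 lists kept their side of the threshold. The deviations of libraries with the same number from their group means correlated at 0.2, -0.31, -0.4 and 0.21 across genes. The 2 negative values involve DPT replicate 2 or DMSO replicate 3, which stood apart. The other 2 lie within the range of 0.13 to 0.24 for unlike numbers among the remaining libraries. These values thus show no pairing by number but do not exclude it.

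With the term for the pair 2140 genes were higher and 2156 lower, with 31 and 4 terms, and the necroptosis list had an adjusted p of 0.0562. Without the pair 2158 were higher and 2169 lower, 277 and 131 at 2-fold, with 57 and 13 terms, and the necroptosis list had an adjusted p of 0.122. The lower variation between replicates (6.3% and 5.5% against 14.9%) goes with the larger counts. With an estimated correlation the adjusted p was 0.718 for DNA replication, 0.442 for p53 targets and 0.693 for necroptosis, and 11 lists lost their call. With fry 9 lists lost theirs: DNA replication (0.267), necroptosis (0.223), NF-kB cytokines (0.132), the integrated stress response (0.309), SRF and YAP targets (0.0937), cholesterol synthesis (0.113), sarcomatoid markers (0.0625), mitochondrial transcripts (0.0675) and endothelial markers (0.0675). Mesothelial markers gained it (0.00202), as they did with library totals only (0.0373), the stricter filter (0.0186) and limma-trend on either scale (0.00278 and 0.00293). Fry does not compare a list with other genes.

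Leaving out each library in turn gave 332 to 1183 genes higher and 311 to 1108 lower, 77 to 239 and 43 to 113 at 2-fold, and 0 to 54 and 0 to 14 terms. The adjusted p of lists ranged from 0.00409 to 0.895 for mitosis, from 1.12e-06 to 0.104 for DNA replication and from 0.00409 to 0.304 for necroptosis. Of 66 named genes that were called, 39 kept the call in all 8 of these fits and 27 lost it in at least 1. On simulated counts with 4 libraries per group the fit without a covariate recovered 50% of 1.5-fold changes, and with the term for the pair this share was 90%. These changes were set in genes of at least 5 CPM, and each share rests on the dispersions of its own fit. Several immune and endothelial markers were too low to test.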

Other observations

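Of the tests in this part, the splits for the number of genes and for the number at 2-fold, the splits for single lists, and the tests of the immediate-early and cytokine genes without the pair, of tubulins, of mitosis and of fibroblast markers, were chosen only after the result was seen.

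Several annotation terms among genes that rose at least 2-fold named signalling at the cell surface. The term cell surface held 14 of 342 tested genes (adjusted p = 0.0269), and JAK-STAT signaling held 8 of 99 (adjusted p = 0.0319), with IL24, CDKN1A and CSF2 among them. Cell migration in sprouting angiogenesis held 4 of 17 (adjusted p = 0.0269), with KDR among them. Skeletal muscle cell differentiation held 5 of 25 (adjusted p = 0.0109), all of them transcription factors, including ATF3 and FOS. Some list members were too low to test. Summed over 4 libraries, CCL20, a chemokine, had 6 counts in DMSO and 59 in DPT. The survival gene BCL2A1 had 1 and 40 and the cytokine TNF 0 and 15. CNN1, a smooth muscle calponin on the SRF and YAP list, had 13 and 60, against the fall of that list. VCAM1, an NF-kB list member also too low to test, went the other way, with 53 counts in DMSO and 11 in DPT. These genes were chosen after their values were seen and were not tested.

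Other splits of the 8 libraries into 4 and 4 gave 0 genes at most, where the real split gave 1387 (1 of 35 splits gave as many). That share is the smallest that 35 splits can give. The other splits mix DPT with DMSO libraries, so a difference between the groups widens the spread within their sides. The splits thus argue against chance for that count but do not exclude it. With 0 genes called, the other splits had none to count at 2-fold (real split 214, highest other 0, 1 of 35) or to test for annotation terms (16, 0 and 1 of 35). These counts therefore give no test of their own. For the number of lists chance cannot be excluded: the real split gave 12, the highest other split gave 18, and 11 of 35 gave as many. All 10 other splits with as many put DMSO replicate 3 and DPT replicate 2 on one side, which points to the structure of the libraries. The splits that part them, 20 with the real one, gave at most 10 lists otherwise, and with the term at most 10 against 13, but 20 are too few for a share under 0.05. Without the pair there are too few splits (10) for a share under 0.05; the real split gave 4327 genes and the highest other 0. With the term there are too few as well (20); the real split gave 4296 and the highest other 1.

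For single lists that passed with all 8 libraries, a p as small as the real one came from 1 of 35 splits for immediate-early, ribosome biogenesis and p53 genes. That is the fewest that 35 splits can give, it was not adjusted over the lists, and the lists were taken because they passed, so chance is not excluded for single lists. For p53 targets the next smallest p was 0.0199, against 0.00606 in the real split. Of the other 9 lists, 4 splits gave as small a p for sarcomatoid markers, 5 for endothelial markers, 6 for NF-kB cytokines, 9 for SRF and YAP targets, 9 for mitochondrial transcripts, 15 for DNA replication, 15 for the integrated stress response, 16 for necroptosis and 17 for cholesterol synthesis. With the term, where 20 splits are too few, the numbers were 2 for DNA replication, 5 for SRF and YAP targets, 8 for mitochondrial transcripts, 10 for cholesterol synthesis, 19 for interferon-stimulated genes and 1 for the other 8 lists that passed.

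Immediate-early and NF-kB cytokine genes were higher in DPT, with a median log2 change of 0.70 over 49 genes. Sequence bias and the pair of libraries are argued against as the whole cause. The median was 0.67 after removal of GC content and length trends and 0.69 without the pair. With library totals only it was 0.74. The TMM factors ran only from 0.9773 to 1.0189, so leaving them out could hardly lower the median and was no real test of composition. Handling of the DPT cultures at harvest may also raise such genes. The medians of the 4 DPT libraries against the DMSO mean ran from 0.25 to 0.99 (SD 0.34), the lowest being DPT replicate 2, and handling stays open because it cannot be told apart from the treatment in this design. A response to DPT itself stays open too.

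Collagens and PDGFRB fell while cytokines rose, and a lower share of fibroblast-like cells in the DPT cultures may be considered. Of 10 fibroblast markers with the term for the pair, 7 fell, among them FBN1 (2095 to 1067 CPM), but 2 rose, VIM (5277 to 7278 CPM, 0.47 log2, SE 0.0373) and SNAI2 (6.22 to 11.1 CPM, 0.89 log2, SE 0.14). H2452 cells may themselves express these markers, so the 2 that rose do not rule out a lower share, and a change within the main cells stays open beside it. Sarcomatoid list members too low to test did not fall. Summed over 4 libraries, LUM had 0 counts in DMSO and 0 in DPT, PDGFRA 3 and 12, COL6A3 12 and 25 and FAP 28 and 61. Counts this low do not decide the question.

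Free tubulin is known to lower the messages of tubulin, and all isotypes might then fall together. With the term for the pair 4 isotypes fell and 3 rose, but the division of reads between near-identical isotypes is uncertain and the median over the isotypes was -0.11 log2, so such a fall stays open, above all for TUBB and TUBA1B, which fell. A hypothesis that cells had gathered in mitosis at 48 h would need the mitosis genes to be higher together. Their median change with the term was 0.019 log2 (SD over members 0.19), with 7 higher and 6 lower (3 and 8 in the 6 libraries), which argues against a common rise at this time, though message levels do not measure the share of cells in mitosis.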
